A study of Mus musculus with 9 samples.

How the data were processed

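MicroRNA libraries were made from total RNA of left ventricles of male mice aged 6 months, in 3 groups of 3 libraries: non-transgenic C57BL/6J mice (NTG), CaNrf2-Low (TG-Low) and CaNrf2-High (TG-High). Groups and replicate numbers (0, 1 and 2) come from the labels. The labels do not state that each library came from a separate animal, so p-values measure only the spread between these samples, which may be technical. The submitters' processing notes name bcl2fastq 1.8.4, Trim Galore 0.4.0, Novoalign, SAMtools and DESeq2 1.18.1, and the genome build mm10 (GRCm38). The role and order of these tools, the counting tool, the use of strand in counting and the miRNA annotation are not given in the sources used here.

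The deposited values are 1 table of 621 mature miRNAs. Per the file headers, it holds a raw read count of each miRNA in each of the 9 libraries, not normalized. The authors added a mean normalized signal per miRNA (the mean of counts divided by size factors), which was used here to set an abundance minimum of 10 for 1 alternative list test. The authors also deposited a log2 fold change of both transgenic lines against NTG with its standard error, a Wald statistic as a score, and a p-value with its adjusted p. The deposited adjusted p equals a Benjamini-Hochberg adjustment over all 621 rows. Columns of samples without a label numbered 0.

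Total counts ranged from 3.62 M (TG-High replicate 2) to 11.7 M (M is 1e6 counts) (TG-High replicate 1). Counts of libraries of 1 group differed by more than sampling noise (chi-square per degree of freedom from 44.5 to 456), so each library was kept as a replicate.

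The main test was edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16, limma 3.58.1, R 4.3.3) with trimmed mean of M values (TMM) scaling, on the rows that filterByExpr kept with a minimum count of 10. This kept 509 rows and left out 112. TG against NTG was fitted with 2 groups, the transgenic lines together, and the other 3 contrasts with a 3-group model in which all 9 libraries share 1 estimate of the spread. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Abundances are counts per 1e6 (CPM) with TMM scaling, and principal components used log2 CPM with a prior count of 2. The fits were tested on simulated data with 200 changed miRNAs. The TG against NTG fit called 50.7% of changes of 1.5-fold, 78.0% of 2-fold and 100% of 4-fold among 494 tested rows, and 5.26% of its calls were unchanged. For TG-High against NTG it called 28.1% of changes of 1.5-fold and 61.5% of 2-fold among 494 rows. For TG-Low against NTG these were 27.7% and 75.4% among 496 rows, and for TG-High against TG-Low 28.4% and 71.6% among 496 rows.

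Lists of 15 kinds were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, each adjusted over the 15. They were myomiRs, hypertrophy and pressure overload, matrix and fibrosis, miRNAs described as targeting Nfe2l2 or Keap1, redox- and hypoxia-responsive miRNAs, and markers of blood cells, endothelium, fibroblasts, smooth muscle, and epithelial and neural tissue. The others were the let-7 family, the miR-17~92 clusters, the miR-15/16 family, the imprinted Dlk1-Dio3 cluster and the Sfmbt2 intron cluster. Members were matched by miRNA name, both arms and all copies, and some belong to more than 1 list. Camera compares the members of a list with the other miRNAs. Fry asks whether the members changed, without that comparison, and was run with all 9 libraries only. Several marker miRNAs are also made by heart muscle, miR-486 for example.

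The lists, the main tests of the comparisons and lists, and the rule for named miRNAs were fixed before the data were examined. The tests of blood miRNAs, rows at 0, neighbouring hairpins and the size of change in each line were chosen after. The rule names the 12 miRNAs with the smallest adjusted p in each direction in TG against NTG, list members that pass, 13 always-named miRNAs of heart, stress and blood, and the 5 most abundant. miR-31-3p, miR-455-5p, miR-148a-3p, miR-451b and the miRNAs of the TG-High comparisons outside the lists were named after their values were seen. miR-208b-5p was left out by the filter.

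Alternatives were DESeq2 size factors, DESeq2's Wald test (DESeq2 1.42.0), no filter on low counts, each library left out in turn, the replicate number as a block, leaving out the 5 most abundant miRNAs, other thresholds and adjustments, 1 row per miRNA, and other correlations, ranks or minimums for the lists. Unchanged groups were simulated 100 times against shared controls for the overlap of the lines. Rows were called near-identical where log2 counts plus 1 differed by less than 0.03 in every library and the mean count was at least 8. Hairpin positions come from GENCODE M21 on GRCm38, the build of the submitters' processing notes, and 595 of the 621 rows matched a hairpin gene by name. Python 3.11.15 was used for positions and plots.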

Results

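MicroRNA sequencing of the left ventricle was carried out of male mice aged 6 months, in 3 groups of 3 libraries (9 in all). The groups were non-transgenic C57BL/6J mice (NTG) and mice of the CaNrf2-Low and CaNrf2-High lines, called TG-Low and TG-High here. Nrf2, encoded by Nfe2l2, is a transcription factor that switches on antioxidant genes. The series title concerns cardiac miRNAs that depend on Nrf2, and the submitters compared both lines together with NTG. The level of the Nrf2 transcript was not analysed here. Total counts over 621 mature miRNAs were 8.37 ± 1.56 M in NTG, 8.31 ± 0.299 M in TG-Low and 7.45 ± 4.05 M in TG-High (mean ± SD, n = 3 each, where M is 1e6 counts). The least deep library was TG-High replicate 2 (3.62 M) and the deepest was TG-High replicate 1 (11.7 M). The 5 most abundant rows were miR-126b-5p, miR-126a-3p, miR-143-3p, miR-22-3p and miR-378a-3p, which held 48.8% to 55.8% of the counts of a library. The rows of miR-126b-5p and miR-126a-3p held near-identical counts, and their hairpins overlap on opposite strands. On the first principal component of log2 abundance, which held 34.2% of the variance, NTG libraries lay between -8.24 and -3.73. TG-Low libraries lay between -3.02 and 3.40, and TG-High libraries between 4.50 and 6.92.

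The comparison of both transgenic lines with NTG asks which cardiac miRNAs differ in mice that carry the transgene. Both arms of miR-671 and both arms of miR-22 rose in transgenic hearts, together with miR-361-3p, miR-24-1-5p and miR-193b-3p. miR-215-5p fell, as did miR-92a-3p, both arms of miR-221, miR-155-5p, a miRNA of immune activation, and miR-194-5p. miR-671-5p was 2.69-fold higher, from 18.7 ± 2.01 counts per 1e6 (CPM) in NTG to 43.6 ± 11.7 in TG-Low and 57.2 ± 7.54 in TG-High (mean ± SD, n = 3). miR-22-3p, an abundant miRNA of heart muscle, was 1.56-fold higher, from 48115 ± 1867 CPM in NTG to 73745 ± 6465 in TG-Low and 76277 ± 9149 in TG-High. miR-215-5p was 2.35-fold lower, from 86.8 ± 5.52 CPM in NTG to 40.8 ± 4.55 in TG-Low and 32.8 ± 5.71 in TG-High.

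By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 44 of 509 tested miRNAs passed an adjusted p of 0.05, 24 higher and 20 lower. The smallest absolute log2 fold change among them was 0.41, and 11 changed at least 2-fold. In 42 of the 44, all 6 transgenic libraries lay beyond all 3 NTG libraries. This held for 88 of the 509 miRNAs, where chance gives 2.38%. The log2 fold changes of those that rose were 1.43 ± 0.22 (SE) for miR-671-5p, 1.24 ± 0.18 for miR-671-3p, 0.94 ± 0.15 for miR-361-3p, 0.76 ± 0.12 for miR-22-5p and 0.64 ± 0.10 for miR-22-3p, all at an adjusted p of 0.00379. miR-24-1-5p rose by 0.88 ± 0.14 at the same adjusted p, and miR-3074-1-3p by 0.83 ± 0.14 (adjusted p = 0.00457). The hairpins of miR-24-1 and miR-3074-1 overlap on opposite strands. miR-193b-3p rose by 0.87 ± 0.16 (adjusted p = 0.00779). Of those that fell, miR-215-5p had a log2 fold change of -1.23 ± 0.15 (adjusted p = 0.00211), miR-92a-3p -0.63 ± 0.11 (adjusted p = 0.00713), miR-221-3p -0.84 ± 0.17 (adjusted p = 0.0133) and miR-155-5p -0.88 ± 0.18 (adjusted p = 0.0158). miR-221-5p (-0.81), miR-224-5p (-0.67), miR-374b-5p (-0.86) and miR-194-5p (-1.06) fell at adjusted p values up to 0.0176. miR-374c-3p carried near-identical counts to miR-374b-5p. miR-31-3p (1.05), miR-34c-5p (1.04), miR-455-5p (0.79) and miR-148a-3p (0.56) rose. The count fell to 14 without NTG replicate 0, to 16 without NTG replicate 2, to 22 without TG-High replicate 1 and to 26 without TG-High replicate 0, and rose to 108 without TG-Low replicate 2. Of the 44, 10 passed with every library left out in turn, namely both arms of miR-671 and of miR-22, miR-361-3p, miR-24-1-5p, miR-3074-1-3p, miR-193b-3p, miR-215-5p and miR-92a-3p.

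**Figure D1:**
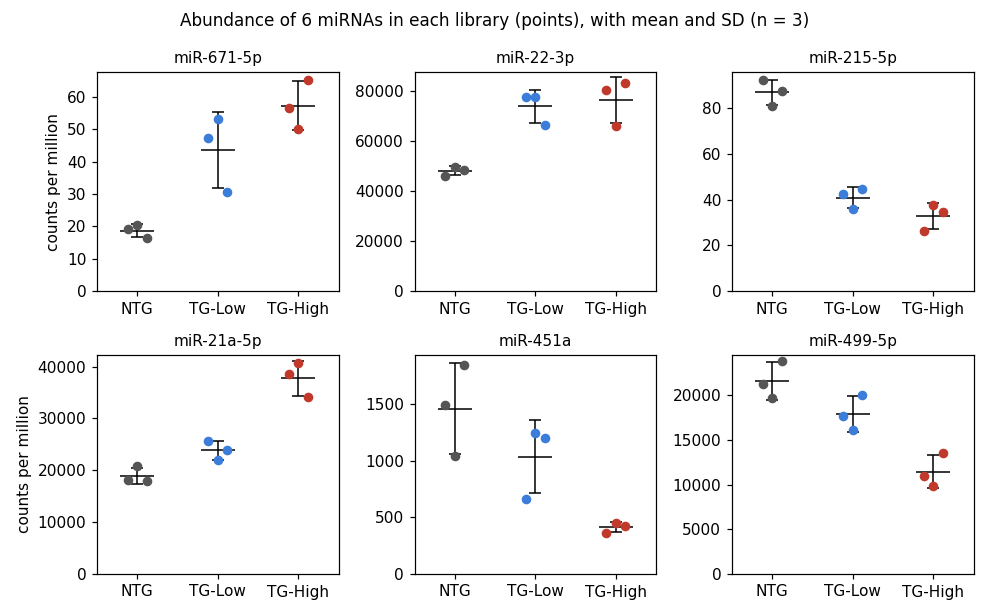
Abundance of 6 miRNAs in CPM (vertical axes, linear, starting at 0) in the NTG, TG-Low and TG-High libraries. Each point is a library, horizontal bars are means and whiskers are SD (n = 3). miR-671-5p and miR-22-3p lie above, and miR-215-5p below, every NTG library in all 6 transgenic libraries, and miR-451a averages 1458 in NTG and 411 in TG-High.

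In genome build GRCm38, the hairpin of miR-671 lies on chromosome 5 from 24592114 to 24592211 on the plus strand, over an exon of Chpf2. That of miR-22 lies on chromosome 11 from 75463716 to 75463810, plus strand, over exons of Mir22hg and Tlcd2. The hairpin of miR-361 lies on the minus strand of chromosome X from 113074824 to 113074893, in an intron of Chm. That of miR-215 lies on chromosome 1 from 185313581 to 185313692, plus strand, over an exon of the antisense transcript 2010103J01Rik. The hairpin of miR-24-1 lies on chromosome 13 from 63301208 to 63301275, plus strand, over an exon of 2010111I01Rik.

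Among the lists fixed beforehand, 12 measured rows were endothelial markers, of which 3 fell (miR-221-3p, miR-221-5p and miR-92a-3p) and 9 did not pass, with 5 lower when adjusted over the list alone. Camera placed this list lower than other miRNAs (adjusted p = 0.00958), a call lost with a correlation estimated from the data (adjusted p = 0.883 with an estimated correlation) and with 1 row per miRNA (adjusted p = 0.0640). The most abundant endothelial miRNA, miR-126a-3p, had a log2 fold change of -0.02 (adjusted p = 0.931). Of 19 rows of the miR-17~92 family clusters, which promote cell proliferation, miR-92a-3p, miR-20a-5p (-0.57) and miR-25-3p (-0.56) fell and 16 did not pass, with 6 lower when adjusted over the list alone (camera adjusted p = 0.00958, and adjusted p = 0.883 with an estimated correlation). miR-92a belongs to both lists. The imprinted Dlk1-Dio3 cluster had 47 measured rows, of which 37 had positive log2 fold changes (median 0.31) and 0 passed edgeR's test (9 at an unadjusted p under 0.05, and 3 past DESeq2's Wald test), also 0 when adjusted over the list alone. Camera placed it higher, with an adjusted p of 0.00958 (adjusted p = 0.930 with an estimated correlation, which was 0.670). TG-Low replicate 2 stood apart in this cluster, with a median log2 difference from the NTG mean of -0.60, where the other 5 transgenic libraries had 0.31 to 0.53. Without NTG replicate 2 the camera calls of the miR-17~92 and Dlk1-Dio3 lists were lost (adjusted p = 0.103 each). By fry the endothelial list (adjusted p = 0.0391) and the miR-17~92 list (0.0398) passed, both lower, and the Dlk1-Dio3 list did not (0.579).

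The let-7 family had 20 measured rows, of which 3 rose (let-7f-1-3p, let-7c-1-3p and let-7i-3p) and 3 fell (let-7j, let-7g-5p and let-7d-5p), with 3 higher and 4 lower when adjusted over the list alone (camera, lower, adjusted p = 0.864, with a median of -0.09 and a mean of 0.05). Of 25 rows of miRNAs described in hypertrophy and pressure overload, 5 rose and 2 fell, with 7 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.693). Those that rose were miR-21a-5p, miR-23b-3p, miR-27b-5p, miR-24-1-5p and miR-24-2-5p, and those that fell were both arms of miR-221. Both arms of a hairpin count as members, and miR-27b-3p, more abundant than miR-27b-5p, had 0.25 (edgeR adjusted p = 0.0978). miR-21a-5p, a miRNA induced in stressed hearts, rose by 0.70 ± 0.20 (adjusted p = 0.0495). Its call was lost with DESeq2 size factors (adjusted p = 0.0543), with no filter on low counts (adjusted p = 0.0501) and with the replicate number as a block (adjusted p = 0.0770). It was also lost without the 5 most abundant miRNAs (adjusted p = 0.0622), with 1 of each pair of near-identical rows (adjusted p = 0.0522), and without any 1 of the NTG or TG-High libraries. The call of miR-24-2-5p (0.46 ± 0.13, adjusted p = 0.0495) was lost with DESeq2 size factors (adjusted p = 0.0530) and with the replicate number as a block (adjusted p = 0.0531). It was also lost without the 5 most abundant miRNAs (adjusted p = 0.0553), and without any 1 of the NTG or TG-High libraries. The matrix and fibrosis list had 29 rows, with miR-21a-5p higher and miR-30a-3p (-0.43) lower, and 0 when adjusted over the list alone (camera adjusted p = 0.297). Of 26 redox- and hypoxia-responsive rows miR-34c-5p rose and miR-155-5p fell, with 3 higher and 4 lower when adjusted over the list alone (camera, lower, adjusted p = 0.864, with a median of 0.02 and a mean of -0.01). Of 25 rows of miRNAs described as targeting Nfe2l2 or Keap1, miR-155-5p fell and 24 did not pass, with 3 lower when adjusted over the list alone (camera adjusted p = 0.437). Of 16 rows of the miR-15/16 family, miR-322-3p (-0.49) and miR-503-5p (-0.48) fell, with 1 higher and 2 lower when adjusted over the list alone (camera, lower, adjusted p = 0.864, with a median of -0.06 and a mean of 0.01). The call of miR-322-3p was lost in 8 and that of miR-503-5p in 10 of 15 refits under other settings.

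In the remaining 6 lists 0 rows passed edgeR's test, over all miRNAs or when adjusted over the list alone. DESeq2's Wald test called miR-144-5p of the blood list (adjusted p = 0.0135) and miR-214-5p of the fibroblast list (adjusted p = 0.0249). At an unadjusted p under 0.05 edgeR had 5 blood, 4 myomiR, 1 fibroblast and 1 epithelial or neural row, and 0 in the other lists. They were the 14 rows of myomiRs of heart and striated muscle (camera adjusted p = 0.825), 14 of blood cells (0.460), 8 of fibroblasts (0.825), 4 of smooth muscle (0.761), 6 of epithelial and neural tissue (0.761) and 5 of the Sfmbt2 intron cluster (0.864, lower, with a median of 0.07 and a mean of -0.01). The values of myomiRs were 0.56 for miR-1a-3p (adjusted p = 0.135), 0.15 for miR-208a-3p (0.369), 0.98 for miR-208b-3p (0.332), 0.18 for miR-133a-3p (0.849) and -0.56 for miR-499-5p (0.0930). miR-133a-3p (1.63 CPM over all libraries) and miR-1a-3p (111 CPM) each come from more than 1 hairpin gene. Whether reads that match several hairpin genes were counted is not given in the sources used here, so these rows may not measure the whole mature miRNA. Rows without a match to the annotation were not checked for copies. The same limit on what is measured holds for other rows from more than 1 hairpin gene, among them miR-29b-3p and miR-194-5p. The median abundance of the 19 rows of this kind was 16.9 CPM, and that of 31 arms that differ between copies was 18.3 CPM. For single-copy hairpins it was 142 CPM over 164 major arms and 7.16 CPM over 164 minor arms, and these medians do not settle the question. The rows of miR-29a, miR-29b and miR-29c ranged from -0.47 (miR-29b-2-5p) to 0.39 (miR-29c-5p), and miR-34a-5p had -0.45 (adjusted p = 0.167). The erythroid miRNAs miR-144-5p and miR-451a had log2 fold changes of -1.34 (adjusted p = 0.0510) and -1.01 (adjusted p = 0.106).

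The authors' deposited table of the same comparison holds 83 miRNAs past an adjusted p of 0.05, 37 higher and 46 lower. All 44 edgeR calls are among the 83 of the authors' deposited table, with the same sign. In the authors' deposited table miR-671-5p has a log2 fold change of 1.42 (SE 0.22, adjusted p = 3.6e-08) and miR-215-5p -1.24 (SE 0.17, adjusted p = 4.2e-11). Of the 46 lower miRNAs of the authors' deposited table, 8 were at 0 in all 6 transgenic libraries with at most 9 counts in any NTG library, and edgeR's filter on low counts left these out. An example from the authors' deposited table is miR-451b, with counts of 6, 3 and 5 in the NTG libraries, for which a fold change cannot be measured from counts of 0.

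In TG-Low against NTG, the question is what the Low line shows by itself. miR-361-3p, both arms of miR-671, both arms of miR-22, miR-24-1-5p and miR-3074-1-3p rose, and miR-215-5p fell. miR-361-3p was 2.10-fold higher, at 599 ± 107 CPM in TG-Low and 285 ± 4.17 CPM in NTG (mean ± SD, n = 3), with a log2 fold change of 1.07 ± 0.15 (edgeR adjusted p = 0.00884). The log2 fold changes were 1.23 ± 0.21 for miR-671-5p (adjusted p = 0.0171), 0.62 ± 0.11 for miR-22-3p (adjusted p = 0.0185) and -1.09 ± 0.17 for miR-215-5p (adjusted p = 0.0102).

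These were the 8 miRNAs of 509 past the threshold, 7 higher and 1 lower, with 88 at an unadjusted p under 0.05. Among the lists, camera placed the endothelial markers and the miR-17~92 clusters lower (adjusted p = 0.00930 each, and adjusted p = 0.876 for both with an estimated correlation). In each, 0 members passed edgeR's test over all miRNAs (3 endothelial and 5 miR-17~92 rows at an unadjusted p under 0.05), while 3 were lower when adjusted over the list alone and 3 passed DESeq2's Wald test. The endothelial call was lost without NTG replicate 1 (adjusted p = 0.0806), NTG replicate 2 (0.105), TG-Low replicate 0 (0.0535) or TG-Low replicate 1 (0.0785). The miR-17~92 call was lost without NTG replicate 2 (0.142) or TG-Low replicate 0 (0.0535). By fry neither list passed (adjusted p = 0.168 each). DESeq2 called 38 miRNAs in all. miR-92a-3p had -0.54 (adjusted p = 0.0519) and miR-221-3p -0.63 (adjusted p = 0.0636). Without TG-Low replicate 1, edgeR called 0 miRNAs (67 at an unadjusted p under 0.05, and 15 by DESeq2), and without TG-Low replicate 2 it called 18, so 0 of the 8 passed with every library left out in turn. With no filter on low counts 21 miRNAs passed, of which 9 were at 0 in all libraries of a transgenic line.

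In TG-High against NTG, the same question for the High line, miR-21a-5p and both arms of miR-34b and miR-34c, p53-responsive miRNAs, rose. miR-34a-5p had -0.49 (edgeR adjusted p = 0.206). Among the miR-34b and miR-34c arms, miR-34c-5p alone passed with every library left out in turn. The other arms had low counts, and the most abundant of them, miR-34b-3p, was at 3.56 to 13.1 CPM across the libraries. Erythroid miR-144 and miR-451a fell, together with both arms of miR-150, a lymphocyte miRNA, both arms of miR-335, miR-155-5p, miR-200c-3p and miR-499-5p, a miRNA from the myosin gene Myh7b. miR-21a-5p was at 37740 ± 3362 CPM in TG-High and 18952 ± 1543 in NTG (mean ± SD, n = 3), a log2 fold change of 0.99 ± 0.11 (edgeR adjusted p = 0.000724). miR-451a was at 411 ± 43.8 CPM in TG-High and 1458 ± 402 in NTG, 3.55-fold lower (log2 fold change -1.83 ± 0.26, adjusted p = 0.00122). miR-499-5p was at 11462 ± 1889 CPM in TG-High and 21620 ± 2104 in NTG (-0.92 ± 0.14, adjusted p = 0.00161).

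Of 509 miRNAs, 93 passed, 45 higher and 48 lower, and 32 changed at least 2-fold. The log2 fold change of miR-150-5p was -1.08 ± 0.13 (adjusted p = 0.000724), that of miR-335-5p -1.31 ± 0.19 (adjusted p = 0.00155) and that of miR-200c-3p, an epithelial miRNA, -2.15 ± 0.40 (adjusted p = 0.00484). miR-34c-5p rose by 1.22 ± 0.25 (adjusted p = 0.00810) and miR-671-5p by 1.61 ± 0.21 (adjusted p = 0.00117). Of 14 blood cell rows, 5 fell (both arms of miR-144 and miR-150, and miR-451a), 1 rose (miR-223-5p, 0.93, a myeloid miRNA) and 8 did not pass, with 5 lower and 1 higher when adjusted over the list alone. Camera gave the blood list an adjusted p of 0.0258, lost with the estimate (adjusted p = 0.369 with an estimated correlation), without NTG replicate 1 (adjusted p = 0.0579) and without TG-High replicate 2 (adjusted p = 0.0521). The myeloid and leukocyte rows miR-223-3p and miR-142a-3p had values of 0.42 (adjusted p = 0.177) and 0.41 (adjusted p = 0.268). Of 25 rows described as targeting Nfe2l2 or Keap1, both arms of miR-144 and miR-155-5p fell, also 3 when adjusted over the list alone (camera adjusted p = 0.0612). The miR-144 arms are on the blood list too.

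Of the 12 endothelial rows 6 fell in TG-High, among them both arms of miR-221 and the miR-126a-5p arm (-0.39), with 7 lower when adjusted over the list alone (camera adjusted p = 0.0211, and adjusted p = 0.620 with an estimated correlation). That call was lost without NTG replicate 1 (adjusted p = 0.0579) and without TG-High replicate 2 (adjusted p = 0.0521). The counts of miR-126a-5p are near-identical to those of miR-126b-3p, another of the 6, and DESeq2's Wald test called 4 of the 6, without these rows (adjusted p = 0.0572 for miR-126a-5p). The more abundant miR-126a-3p had -0.07 (adjusted p = 0.776). Of 47 Dlk1-Dio3 rows 5 rose, namely miR-434-5p, miR-136-5p, miR-376b-5p, miR-381-3p and miR-377-3p, and 0 passed when adjusted over the list alone (camera adjusted p = 0.00379, and adjusted p = 0.620 with an estimated correlation). Of 25 hypertrophy rows 7 rose and 3 fell, with 10 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.135). Of 29 matrix and fibrosis rows both arms of miR-21a rose, and miR-29c-3p (-0.55, adjusted p = 0.0272), miR-29b-2-5p (-0.72, adjusted p = 0.0191), miR-30a-3p, miR-30d-5p and miR-101a-3p fell. In that list 2 were higher and 7 lower when adjusted over the list alone (camera adjusted p = 0.135), and miR-29a-3p and miR-29b-3p had -0.08 (adjusted p = 0.687) and 0.19 (adjusted p = 0.792). The row of miR-29b-3p held 0.96 to 2.46 CPM and comes from more than 1 hairpin gene, so it may not measure the whole mature miRNA. Of 26 redox- and hypoxia-responsive rows the 4 arms of miR-34b and miR-34c rose and both arms of miR-144, miR-155-5p and miR-200c-3p fell, with 4 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.460). Of 19 miR-17~92 rows 4 fell, and 5 when adjusted over the list alone (camera adjusted p = 0.0543), and of 20 let-7 rows 3 rose and 4 fell, with 3 higher and 5 lower when adjusted over the list alone (camera, higher, adjusted p = 0.986, with a median of -0.04 and a mean of 0.06). Of 16 miR-15/16 rows miR-16-1-3p rose and miR-503-5p fell, with 2 higher and 2 lower when adjusted over the list alone (camera, higher, adjusted p = 0.985, with a median of -0.02 and a mean of 0.04). In the other lists miR-499-5p of the myomiRs, miR-145a-3p of smooth muscle and miR-200c-3p of epithelial tissue fell and miR-214-5p of fibroblasts rose, with camera adjusted p values of 0.985, 0.207, 0.258 and 0.403. The test placed the myomiRs lower, where their median was 0.10 and their mean 0.08. In the Sfmbt2 intron cluster 0 of 5 rows passed edgeR's test, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 (camera adjusted p = 0.573). Fry placed the blood (adjusted p = 0.000216) and endothelial (0.0193) lists lower. It also placed the Nfe2l2 or Keap1, redox and miR-17~92 lists lower (fry adjusted p = 0.039 each). The Dlk1-Dio3 list did not pass fry (0.272). The count of 93 fell to 37 without TG-High replicate 0, to 44 without TG-High replicate 1, to 52 without NTG replicate 2 and to 54 without NTG replicate 0. Of the 93, 31 passed with every library left out in turn, among them miR-21a-5p, miR-451a, both arms of miR-144 and of miR-335, miR-150-5p and miR-499-5p.

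**Figure D2:**
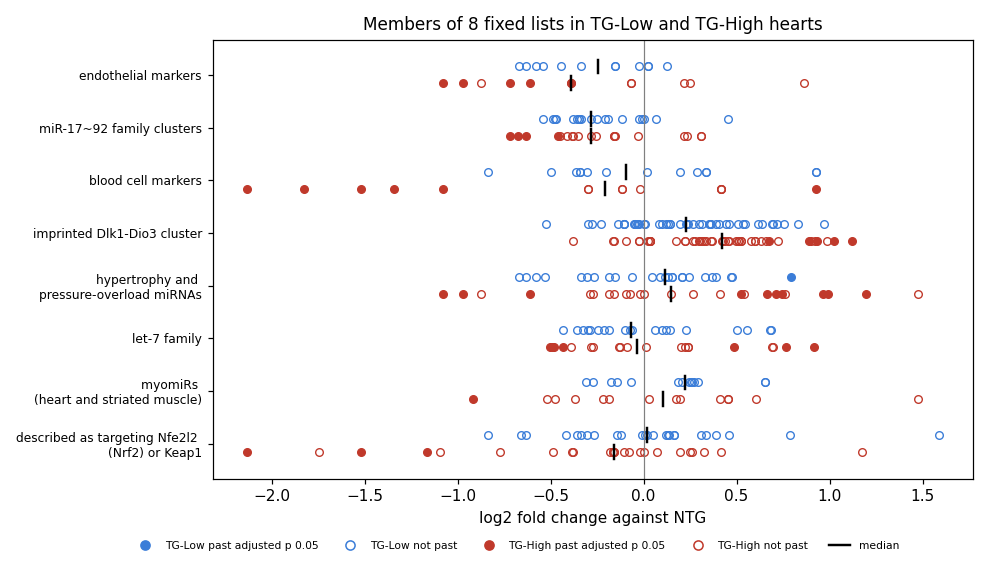
Log2 fold change against NTG (horizontal axis) of each measured member of 8 fixed lists in TG-Low (blue) and TG-High (red). Filled circles passed edgeR's adjusted p of 0.05, open circles did not, and black bars are medians. In the blood list miR-144-5p reaches -2.13 in TG-High, while miR-223-5p of the same list has 0.93.

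All 8 miRNAs called in TG-Low were called in the same direction in TG-High, 7 higher and 1 lower. Independent lists of these sizes would share 0.713, and unchanged groups simulated against shared controls shared 0.01 on average (at most 1 in 100 simulations). The simulated groups held no changed miRNA and so give few calls to share. They cannot show how far shared controls raise the overlap of 8 and 93 calls. The 8 also include both arms of miR-671 and of miR-22, and the overlapping hairpins of miR-24-1 and miR-3074-1, so they are not independent rows. Across miRNAs, which are not independent replicates, the log2 fold changes of the lines had a correlation of 0.786, against a simulated 0.494. Their covariance was 0.212 against a simulated 0.0609, a difference of 0.151. The simulated lines also shared their controls, so the simulated values already hold the part that shared controls give when rows vary independently. Rows that vary together in the NTG libraries could still give part of the excess. The 3 NTG libraries cannot be split into 2 sets of 2 to check this.

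TG-High against TG-Low asks where the lines differ. miR-21a-5p was 1.58-fold higher in TG-High, with a log2 fold change of 0.66 ± 0.11 (edgeR adjusted p = 0.0206). The miRNAs that were lower were miR-150-5p (-0.87 ± 0.13, adjusted p = 0.0153), miR-144-3p (-1.22 ± 0.22, adjusted p = 0.0254), miR-451a (-1.33 ± 0.25, adjusted p = 0.0254), both arms of miR-335 and miR-499-5p (-0.65 ± 0.14, adjusted p = 0.0492). miR-335-5p had a log2 fold change of -1.04 ± 0.19 (adjusted p = 0.0254) and miR-335-3p -0.83 ± 0.18 (adjusted p = 0.0492). The hairpin of miR-335 lies in an intron of Mest on chromosome 6, from 30741299 to 30741396 on the plus strand, and that of miR-499 in an intron of Myh7b on chromosome 2, from 155622880 to 155622958 on the plus strand.

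These 7, 1 higher and 6 lower, were all that passed among 509 miRNAs, with 41 at an unadjusted p under 0.05. Of 14 blood cell rows 3 were lower, and 5 when adjusted over the list alone (camera adjusted p = 0.00276, and adjusted p = 0.134 with an estimated correlation). Camera also placed the 25 rows described as targeting Nfe2l2 or Keap1 lower (adjusted p = 0.00862, and adjusted p = 0.399 with an estimated correlation), with miR-144-3p lower and 3 lower when adjusted over the list alone. That call was lost without TG-Low replicate 2 (adjusted p = 0.257). It placed the 4 smooth muscle rows lower (adjusted p = 0.00727, and adjusted p = 0.399 with an estimated correlation), with 0 past edgeR's test (3 at an unadjusted p under 0.05, and 0 by DESeq2) and 3 when adjusted over the list alone, a call lost without TG-Low replicate 1 (adjusted p = 0.0671). The hypertrophy list (adjusted p = 0.0108, and adjusted p = 0.399 with an estimated correlation) had 1 member past, miR-21a-5p, which was also the 1 when adjusted over the list alone. Its call was lost without TG-Low replicate 0 (adjusted p = 0.126), TG-Low replicate 1 (0.0931) or TG-High replicate 1 (0.113). The Dlk1-Dio3 cluster was placed higher (adjusted p = 0.000947, and adjusted p = 0.594 with an estimated correlation) with 0 members past edgeR's test (0 at an unadjusted p under 0.05, and 0 by DESeq2), also 0 when adjusted over the list alone. This call rested on TG-Low replicate 2, and without that library camera gave an adjusted p of 0.881 with the direction turned to lower. By fry the blood list passed (adjusted p = 0.000841, lower). The Nfe2l2 or Keap1 (0.143), smooth muscle (0.222), hypertrophy (0.312) and Dlk1-Dio3 (0.566) lists did not pass fry. edgeR called 0 miRNAs without TG-High replicate 0 (31 at an unadjusted p under 0.05, and 22 by DESeq2), 2 without TG-High replicate 1 and 4 without TG-High replicate 2. DESeq2's Wald test called 36 with all libraries, of which 21 were at 0 in all libraries of a line.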

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

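The tests of the blood miRNAs below were chosen after the result was seen. The 7 miRNAs that passed edgeR's quasi-likelihood test between TG-High and TG-Low are given for a closer look. Of the 7, 0 passed with every library left out in turn. Their log2 differences were -0.87 for miR-150-5p, 0.66 for miR-21a-5p, -1.22 for miR-144-3p, -1.04 for miR-335-5p, -1.33 for miR-451a, -0.83 for miR-335-3p and -0.65 for miR-499-5p. Of the 10 splits of the 6 transgenic libraries, the real one gave 7 calls and the highest other 1, and 10 splits cannot give a share under 0.05. In 61 results tested for a library far from the rest of the 6 transgenic libraries, miR-1a-2-5p stood out, with TG-High replicate 2 at 4.38 CPM and the others between 2.08 and 2.32 (gap over range 0.859 on the log2 scale). Chance picks out about 1 in 20 such results.

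If the lower miR-144, miR-451a and miR-150 of TG-High came from less whole blood in the samples, the leukocyte miRNAs miR-142a-3p and miR-223-3p would be lower as well. The 95% interval of miR-223-3p begins at -0.0198, above the log2 fold change of miR-150-5p (-1.08), the marker that fell least, which argues against whole blood as the sole source, although a rise of myeloid cells could hide part of it. The low depth of TG-High replicate 2 was also argued against, since all 4 rows (both arms of miR-144, miR-451a and miR-150-5p) passed edgeR's test without it. Of the other erythroid marker, miR-486b-5p had -0.12 in TG-High (95% interval -1.02 to 0.78), above the values of miR-144-3p (-1.52) and miR-451a (-1.83), while miR-486a-5p had -0.30 (-1.93 to 1.33), and heart muscle makes miR-486 as well. A lower share of red cells or lymphocytes alone and a difference between the lines in the heart therefore stay open.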

How the results depend on the processing

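Refits with other scaling, test, filter, block or rows, or with a library left out, were run for all 4 comparisons. None turned the direction of a called miRNA, while the Dlk1-Dio3 list turned in TG-High against TG-Low without TG-Low replicate 2. Other thresholds and adjustments, and 1 row per miRNA, were run for TG against NTG only. So were the list settings other than the estimated correlation, fry and left-out libraries. Leaving out rows at 0 in a whole line, leaving out near-identical copies, and the list tests under scaling, block and left-out libraries were chosen after seeing the data. In TG against NTG, the 44 calls became 83 by DESeq2's Wald test (all 44 among them), 95 at an adjusted p of 0.1, 10 at 0.01, 11 with an absolute log2 fold change of at least 1 and 8 by Bonferroni adjustment, where the last 4 follow from the threshold. In TG-Low against NTG the 8 calls became 38 by DESeq2 and 21 without a low-count filter, and in TG-High against TG-Low the 7 became 36 and 25. Rows at 0 in a whole line made up 10 of the 38, 9 of the 21, 21 of the 36 and 16 of the 25. With no filter, TG against NTG had 66 calls, 17 of them such rows, and TG-High against NTG 110, with 20. By DESeq2, such rows made up 8 of the 83 in TG against NTG and 5 of 101 in TG-High against NTG. Without such rows and with no filter, the counts were 47, 8, 84 and 5 for TG, TG-Low and TG-High against NTG and TG-High against TG-Low.

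Leaving out each library in turn gave 14 to 108 calls for TG against NTG, 0 to 18 for TG-Low (0 without TG-Low replicate 1), 37 to 114 for TG-High and 0 to 10 for TG-High against TG-Low (0 without TG-High replicate 0), and the cause beyond fewer samples was not tested. Of the 3 lists called in TG against NTG, 0 passed at a correlation of 0.05 (3 at an unadjusted p under 0.05) and 0 with an estimated correlation (0 at an unadjusted p under 0.05), and 1 to 3 passed with a library left out (1 without NTG replicate 2). DESeq2 size factors kept 39, 8, 92 and 7 of the 44, 8, 93 and 7 calls and moved the median log2 fold change by at most 0.02. The replicate block gave 35, 11, 75 and 6 calls, and kept 34, 8, 73 and 6 of the 44, 8, 93 and 7. The 10 calls lost under it in TG against NTG include miR-21a-5p (edgeR adjusted p = 0.0770) and miR-24-2-5p (0.0531). They also include miR-503-5p (0.0700), miR-148a-3p (0.0598) and miR-30a-3p (0.0577). Of 9 pairs of libraries with the same number, 3 had a correlation of deviations over 0.1 (range -0.174 to 0.235). In both other groups 1 library correlated best with its own number. These values give no clear sign that the numbers pair the samples, and with 3 libraries per group they cannot exclude it. Of the 15 refits of TG against NTG, miR-21a-5p lost its call in 11, miR-503-5p in 10, miR-24-2-5p in 9, miR-322-3p and miR-30a-3p in 8, and miR-148a-3p and let-7d-5p in 7. Alternatives planned for a table without counts did not apply.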

Other observations

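The tests of rows at 0, of neighbouring hairpins and of the size of change in each line were chosen after the results were seen. Several miRNAs that changed lie in hairpin clusters. On chromosome 13, miR-23b-3p (0.57), miR-27b-5p (0.60) and miR-24-1-5p (0.88) rose in TG against NTG, and the more abundant miR-27b-3p had 0.25 (adjusted p = 0.0978). In the related cluster on chromosome 8, miR-24-2-5p rose (0.46, adjusted p = 0.0495), and miR-23a-3p and miR-27a-3p had -0.21 (adjusted p = 0.291) and -0.08 (adjusted p = 0.709). The difference between these clusters was not tested. In a cluster of 5 hairpins on chromosome X, miR-503-5p (-0.53), miR-542-3p (-0.78) and miR-450b-5p (-0.59) fell in TG-High, where miR-322-3p had -0.47 (adjusted p = 0.0558) and miR-351-5p -0.28 (adjusted p = 0.190). In TG against NTG, miR-503-5p and miR-322-3p fell, and miR-542-3p, miR-450b-5p and miR-351-5p had adjusted p values of 0.0570, 0.128 and 0.195. miR-192-5p (-0.58), miR-194-5p (-1.07) and miR-215-5p (-1.40) fell in TG-High, and miR-192-5p had -0.44 in TG against NTG (adjusted p = 0.0681). Of the let-7 rows called in TG against NTG, those that rose are 3p arms, and let-7g-5p and let-7d-5p, which fell, are 5p arms. This arm pattern was not tested.

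A hypothesis of shared transcription or processing was tested over 214 pairs of hairpins within 10 kb on 1 strand. Their mean product of log2 fold changes in TG-High, each minus the mean over all hairpins, was 0.204. It was at most 0.152 in 10000 shuffles of 326 hairpins (permutation p = 0.0001, one-sided, the smallest these shuffles can give). Without pairs that include a member of the Dlk1-Dio3 list, 74 pairs gave 0.255 (permutation p = 0.0001). These still hold the pair of miR-3544 and miR-3071, whose counts are near-identical to those of list members miR-337-5p and miR-136-3p. Neighbours may thus share part of their change, but hairpins that share chance variation between samples would give the same result, so this does not tie the pattern to the transgene. A second hypothesis was that the changes are larger in TG-High. Of the 44 miRNAs called in TG against NTG, 41 had a larger absolute log2 fold change in TG-High than in TG-Low, and the mean difference in the direction of change was 0.22. The highest of the other labelled divisions of the 6 transgenic libraries gave 0.17, and 20 divisions cannot give a share under 0.05.

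In TG-Low 53 rows and in TG-High 41 rows were at 0 in all 3 libraries, against 0 rows in NTG. Sampling of rare reads is argued against, since the NTG read rates give 0.295 such rows in TG-Low. Loss of expression as the whole source is argued against too, since 0.187% of rows with 10 or more counts in an NTG library (1 of 536) were at 0 in TG-Low, and 61.2% of the rows with fewer. A candidate explanation is a count minimum applied to each line before the tables were joined, as 98.1% of the 53 rows had fewer than 10 counts in every NTG library. Against a strict minimum, 9 of the 61 rows with fewer than 10 counts in every NTG and TG-Low library were not at 0 in TG-Low. Such a minimum would also have had to spare NTG, where 85 rows had fewer than 10 counts in every library and 0 rows were at 0 in all 3. All 18 rows at 0 in TG-Low alone reached 10 or more counts in TG-High.

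Near-identical counts were found in 19 pairs of rows, such as miR-126a-3p and miR-126b-5p, miR-24-2-5p and miR-3074-2-3p, and miR-1a-3p and miR-1b-5p. The rows ranked second in their pair, by mean count and then by name, hold 17.2% of all counts. In the first pair this is miR-126a-3p. The hairpins of 16 pairs overlap on opposite strands, 0 pairs have hairpins that lie apart, and 3 pairs were not matched to the annotation. This argues against reads shared between copies at separate loci. Counting that took no account of strand could give such pairs. Either name of a pair may therefore not be a miRNA of its own in these data, and the ranking does not show which.

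Other splits of the 9 libraries into 6 and 3 test whether grouping by chance gives as many calls. Of 84 splits, 1, the real one, gave as many as the 44 calls of TG against NTG, and the highest other gave 15 (TG-High against the rest). This argues against a chance split of these libraries for that count but does not exclude it. The labels also do not state that the libraries are separate animals. For the 3 lists called by camera, 44 of the 84 splits gave as many and the highest other gave 7, so the splits do not argue against chance there. For TG-Low against NTG the real split of 6 libraries gave 8 calls and the highest other 0. For TG-High against NTG these were 93 and 0. Each of these had 1 split of 10 with as many calls, and 10 splits cannot give a share under 0.05.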
